A study of Mus musculus with 7 samples.

How the data were processed

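Droplet-based single-cell RNA sequencing of sorted islet cells was analysed in 7 libraries, 5 from NOD mice (4 weeks, 2 libraries; 8 weeks, 2 libraries; 15 weeks, 1 library), 1 from Ifngr1-/- mice at 8 weeks and 1 from Rag1-/- mice at 8 to 16 weeks. Per the labels, each library pools female mice and live CD45-positive, CD31-positive and CD45-negative CD90-positive cells. For each library the authors deposited a matrix of unfiltered UMI counts per gene and barcode, made with Cell Ranger against GRCm38 per the submitters' processing notes, and the version is not given in the sources used here. Per the file headers, the matrix of the Rag1-/- library was written by software 3.0.2 and lists 6794880 barcodes, while the others list 737280. The authors also deposited an annotation with a cell type, library and batch for 59250 barcodes under 31 labels, and how it was made is not given in the sources used here. The file names and the annotation give the batches, and the batch of the Ifngr1-/- library rests on the annotation alone.

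Between 69.0% and 79.9% of UMIs lay in annotated barcodes. Barcodes that the annotation marks as aggregates of cells (3662) or as contamination (340) were left out, and so were barcodes without an annotation. The remaining labels named 15 cell types, 12 of them leukocytes, and were used as given. Raw counts were summed per library over the cells of a type, since cells are not replicates. All 33456 genes were read by identifier, 109 symbols were carried by more than 1 identifier, and 32739 identifiers (97.9%) matched GENCODE vM21, which gave coordinates and gene classes. Macrophages, CD4 T cells, CD8 T cells, endothelial cells and mesenchymal cells were chosen before the data were examined, and conventional dendritic cells were added after. Sums ranged from 300682 UMIs (CD8 T cells, 4-week replicate 1) to 22715161 UMIs (endothelial cells, Rag1-/-), and a library entered a fit with at least 20 cells of the type. CPM values of groups compared are scaled by TMM, and CPM of a single library in the description of the target genes are not.

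Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM factors, filterByExpr, Benjamini-Hochberg adjustment within a comparison and cell type, threshold 0.05). Each fit held all libraries and 1 mean per group, which leaves 2 residual degrees of freedom from the 4-week and 8-week pairs. The 15-week, Ifngr1-/- and Rag1-/- groups have 1 library each and are assumed to vary like those pairs. SE is the absolute log2 fold change over sqrt(F). The comparisons were 8-week and 15-week with 4-week NOD, and Ifngr1-/- and Rag1-/- with 8-week NOD. They share libraries (4-week NOD in the first pair, 8-week NOD in 3 of them), so part of any likeness can come from these. A gene without UMIs in a group is given as a bound that takes 3 counts as the floor. Shares of leukocytes were compared by the same edgeR test on cell counts, with the leukocytes of a library as its size, and shares carry exact 95% binomial intervals.

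The script was tested on simulated counts with the libraries' own means, sizes and spread and 200 changed genes. For 8-week against 4-week macrophages it recovered 68 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 6.67% of calls false, and for CD8 T cells 16 and 82. With a single library in 1 group (Ifngr1-/-), 33 and 99 were recovered in macrophages and 10.2% of calls were false, and in endothelial cells 13.3%. Of 100 unchanged random (so not co-regulated) lists in 8-week macrophages, 2 had list-test p under 0.05.

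Gene lists were written in advance and tested with camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01 and adjustment over all lists in a comparison and cell type. Camera was rerun with a correlation estimated from the data, and the rotation test fry was run beside it. There were 26 lists: interferon-gamma response, type I interferon response, MHC class I and peptide loading, MHC class II, inflammatory cytokines and chemokines, resident macrophage, lipid and phagolysosome, monocyte, cell cycle, effector T cell, inhibitory receptor and exhaustion, naive and central memory T cell, regulatory T cell, follicular helper T cell, endothelial adhesion and activation, endothelial capillary identity, extracellular matrix, stromal cytokine and chemokine, dissociation and immediate-early genes, markers of endocrine, acinar, erythroid, B and plasma, T and macrophage cells, and RNA quality (12 mitochondrial transcripts). For each list the members that rose or fell are counted in the whole fit and again when adjusted over the list alone.

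The replicate number names a shared batch per the labels, so it pairs the 4-week and 8-week libraries. Deviations of same-numbered libraries from their group means correlated with r = 0.152 in macrophages, 0.0946 in CD4 T cells, 0.123 in CD8 T cells, 0.323 in endothelial cells and 0.185 in mesenchymal cells. Fits with the number as a block were planned, and for Ifngr1-/- the block with that library in the second batch was added after the data were seen. These fits leave 1 residual degree of freedom. The other planned settings were RLE size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, at most 200 cells per library and type, each 4-week and 8-week replicate left out in turn, 15-week NOD as the control of Rag1-/-, and for shares TMM, all identified cells or non-lymphoid leukocytes as the denominator. Leaving out genes at least 2 times as high in empty droplets (up to 50 UMIs) as in the cells, and leaving the Rag1-/- library out of the fit, were added after the data were seen. The same holds for every setting in conventional dendritic cells.

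Named genes follow a rule fixed in advance. It takes the 5 largest rises and 5 largest falls in macrophages and 3 of each in other types, among genes that pass with a mean of at least 20 CPM, leaving out gene models without a name, antigen receptor segments and Xist. It adds up to 4 members with the smallest p from each list that passes, the genes Ifngr1, Rag1 and Ifng in every library, and the 3 genes with the smallest p where fewer than 5 pass. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Reads were not analysed here.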

Results

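Single cells from pancreatic islets of non-obese diabetic (NOD) mice, an inbred strain that develops autoimmune diabetes spontaneously, were profiled by droplet-based sequencing of 3' mRNA ends with molecular identifiers (UMIs). The cells had been sorted for leukocytes, endothelial cells and stromal cells, so that shares across those classes partly reflect the sort. NOD mice were sampled at 4 weeks (2 libraries), 8 weeks (2 libraries) and 15 weeks (1 library) of age. NOD mice lacking Ifngr1, the ligand-binding chain of the interferon-gamma receptor, were sampled at 8 weeks (1 library), and NOD mice lacking Rag1, which is needed to assemble antigen receptor genes, at 8 to 16 weeks (1 library). All mice were female and each library pooled the islets of several mice, so p-values measure the spread between libraries and not between mice.

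The 7 libraries held between 33483932 and 64255217 UMIs. The authors' annotation named between 7169 and 9409 barcodes per library as cells, with a median of 2380 to 5768 UMIs per cell, the highest in the Rag1-/- library. Of 59250 annotated barcodes, 55248 carried a cell type and 20963 of these were leukocytes. The 15-week, Ifngr1-/- and Rag1-/- groups had 1 library each, and their tests take their spread from the 4- and 8-week pairs. The 4-week and 8-week replicate 1 libraries and the 15-week library came from 1 batch, the 4-week and 8-week replicate 2 libraries from a second, to which the annotation also assigns the Ifngr1-/- library, and the Rag1-/- library from another, whose effect cannot be told apart from the genotype.

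The targeted genes were examined first. Ifngr1 (GRCm38 chromosome 10, 19591949 to 19610229, plus strand, protein coding) was read in macrophages at 278 and 218 CPM in the 4-week libraries, 233 and 205 at 8 weeks, 178 at 15 weeks, 110 in the Ifngr1-/- library and 358 in the Rag1-/- library. Its 3' tags can lie outside the deleted part, so they do not test the label. Rag1 (GRCm38 chromosome 2, 101638282 to 101649501, minus strand, protein coding) gave 0 UMIs in macrophages of every NOD and Ifngr1-/- library and 1 UMI in those of the Rag1-/- library, so this gene does not test its label either. The cells run the way that label says, with 0 of 2393 leukocytes annotated as CD4 or CD8 T cells, B cells or plasma cells. The immunoglobulin gene Igkc had 1 UMI in empty droplets there, against 476 to 25131 in the others.

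The leukocytes of the islet changed from a population mainly of macrophages towards one mainly of lymphocytes with age. Macrophages made up 58.2% ± 12.5 of leukocytes at 4 weeks (SD, n = 2), 34.4% ± 0.764 at 8 weeks (SD, n = 2) and 14.6% at 15 weeks, 62.6% in the Ifngr1-/- library and 82.9% in the Rag1-/- library. CD4 T cells made up 9.45% ± 2.31, 14.3% ± 0.162 and 24.6% at 4, 8 and 15 weeks, 9.26% without Ifngr1 and 0 of 2393 leukocytes without Rag1, which allows a share of up to 0.125%. B cells differed most between replicates, at 0.980% and 24.7% in the 4-week libraries, 7.76% and 23.6% at 8 weeks, 22.1% at 15 weeks, and 1.07% in the Ifngr1-/- library. These limits and the intervals plotted cover counting error only.

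**Figure D1:**
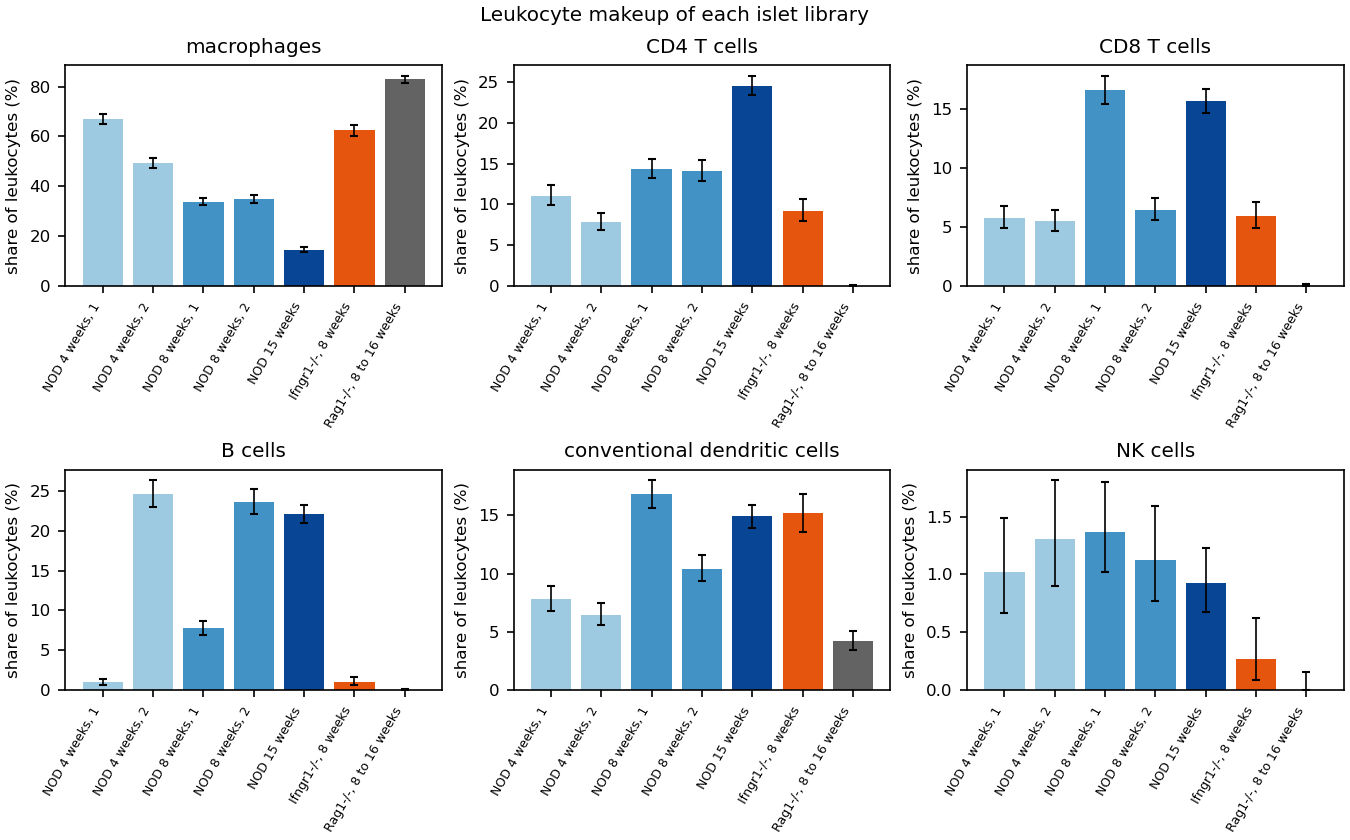
Share of leukocytes (%) for 6 cell types in each of the 7 libraries, with bars for the exact 95% binomial interval of each share. Macrophages fall from 67.0% and 49.3% at 4 weeks to 14.6% at 15 weeks and reach 82.9% in the Rag1-/- library.

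Between 4 and 8 weeks, 0 of 12 leukocyte types passed the edgeR test of composition, with 1 at an unadjusted p under 0.05, plasma cells, and 1 type passed when 4-week replicate 2 was left out. With all identified cells as the denominator, which the sort affects, 7 passed. At 15 weeks, macrophages were lower than at 4 weeks by a log2 fold change of -2.0 ± 0.54 (SE, adjusted p = 0.045), while plasma cells (6.27 ± 0.93, adjusted p = 0.015), gamma-delta T cells (2.02 ± 0.46, adjusted p = 0.045) and type 3 innate lymphoid cells (4.20 ± 1.13, adjusted p = 0.045) were higher. With the batch number as a block, plasma cells alone passed (adjusted p = 0.022), and macrophages, gamma-delta T cells and type 3 innate lymphoid cells had adjusted p = 0.20, 0.052 and 0.052. With TMM factors none of the 4 passed (plasma cells at adjusted p = 0.072), and with all identified cells as the denominator 10 of 12 types did. The 4 types became 1 without 4-week replicate 2, 1 without 8-week replicate 1 and 0 without 8-week replicate 2.

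In the Ifngr1-/- library 0 of 12 types passed against 8-week NOD, with 4 at an unadjusted p under 0.05. The smallest adjusted p belonged to NK cells (log2 fold change -2.21 ± 0.57, adjusted p = 0.074) and type 2 innate lymphoid cells (2.5 ± 0.61, adjusted p = 0.074), and 1 type passed without 4-week replicate 2, 1 without 8-week replicate 1 and 1 without 8-week replicate 2. With all identified cells as the denominator 4 passed. In the Rag1-/- library 11 of 12 types passed, 2 higher and 9 lower, and 7 with TMM factors. CD4 T cells were at least 114-fold lower than at 8 weeks, CD8 T cells at least 91.9-fold and B cells at least 125-fold, taking 3 cells as the floor of the Rag1-/- library. Macrophages rose (1.27 ± 0.47, adjusted p = 0.048) and conventional dendritic cells fell (-1.69 ± 0.53, adjusted p = 0.034). Cells annotated as NKT rose (1.91 ± 0.40) to 12.9%, or 10.3% without cells at macrophage levels of C1q. No cell there was labelled plasmacytoid dendritic, NK, gamma-delta T or innate lymphoid, so their falls and the NKT rise can come from labelling. Of 47 barcodes with at least 2 UMIs of the NK cell genes Ncr1, Klrb1c and Klre1, 46 carried the NKT label. Over non-lymphoid leukocytes (plasmacytoid dendritic cells again at 0), macrophages were higher by 0.53 (adjusted p = 0.016) and conventional dendritic cells lower (-2.41, adjusted p = 0.00064).

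The first comparison asks what changed in the islet between 4 and 8 weeks, when leukocytes accumulate. In macrophages, Vcam1, an adhesion molecule, rose from 36.1 ± 5.35 to 166 ± 34.8 CPM (SD, n = 2 each; log2 fold change 2.20 ± 0.22 SE, adjusted p = 0.024). Cfb, a component of the alternative complement pathway (2.73 ± 0.34, adjusted p = 0.046), rose. So did Il18bp, a decoy for interleukin-18 (2.52 ± 0.34, adjusted p = 0.046), and Dnase1l3, a secreted nuclease (2.14 ± 0.26, adjusted p = 0.046). Cfb, Il18bp and Dnase1l3 did not pass with RLE size factors (adjusted p = 0.064 each) or with the Rag1-/- library left out of the fit (adjusted p = 0.060 each). In mesenchymal cells the chemokines Ccl8 (3.78 ± 0.51, adjusted p = 0.029) and Cxcl9 (1.88 ± 0.27, adjusted p = 0.032) rose. The interferon-induced GTPases Tgtp2 (2.59 ± 0.34, adjusted p = 0.026) and Gbp2 (1.93 ± 0.21, adjusted p = 0.010) rose, and the globin genes fell. In endothelial cells and in CD4 and CD8 T cells no gene passed.

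Genes of the interferon-gamma response were higher together in the 3 non-lymphoid cell types. All 28 measured members of that list were higher in macrophages at 8 weeks, 1 rose (Zbp1, a nucleic acid sensor, 1.29 ± 0.18, adjusted p = 0.046), 27 did not pass, and 25 rose when adjusted over the list alone. Zbp1 did not pass with RLE size factors (adjusted p = 0.064) or without the Rag1-/- library (adjusted p = 0.060). Their median log2 fold change was 1.36 (camera adjusted p = 2.1e-32, and adjusted p = 0.22 with an estimated correlation). In endothelial cells 28 of 29 members were higher, with a median of 1.65 (adjusted p = 8.8e-44, and adjusted p = 0.26 with an estimated correlation). There 0 rose, and 27 when adjusted over the list alone. In mesenchymal cells all 27 were higher, with a median of 1.54 (adjusted p = 1.3e-39, and adjusted p = 0.25 with an estimated correlation). Of those 7 rose, and 24 when adjusted over the list alone. With the batch as a block, 22, 26 and 24 members rose in the 3 types. The medians within each batch were 1.28 and 1.25 in macrophages. In CD4 T cells 20 of 24 members were higher, 0 rose and 3 when adjusted over the list alone, with a median of 0.30 (adjusted p = 6.4e-05, without 8-week replicate 1 0.082, and adjusted p = 0.47 with an estimated correlation). In CD8 T cells the list did not pass (median -0.03, adjusted p = 0.72).

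Cxcl9, a ligand of the T cell chemokine receptor Cxcr3 (GRCm38 chromosome 5, 92321347 to 92328079, minus strand, protein coding), was 459 ± 100 CPM in macrophages at 8 weeks against 114 ± 42.3 at 4 weeks (SD, n = 2 each), a log2 fold change of 2.01 ± 0.28 that did not pass (adjusted p = 0.050). It passed with the block (adjusted p = 2.0e-07), a fit with 1 residual degree of freedom. Likewise the B cell chemoattractant Cxcl13 (GRCm38 chromosome 5, 95956951 to 95961068, plus strand, protein coding) was 432 ± 378 CPM against 13.8 ± 13.8 in macrophages (4.99 ± 0.85, adjusted p = 0.068, and with the block 6.5e-13). In endothelial cells Cd274, which encodes PD-L1 (1.71 ± 0.19, adjusted p = 0.086, and with the block 7.0e-06), Cxcl10 (2.12 ± 0.26, adjusted p = 0.090, and with the block 1.3e-06) and the class I gene H2-Q7 (1.57 ± 0.16, adjusted p = 0.086, and with the block 1.4e-05) had the same pattern of values.

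**Figure D2:**
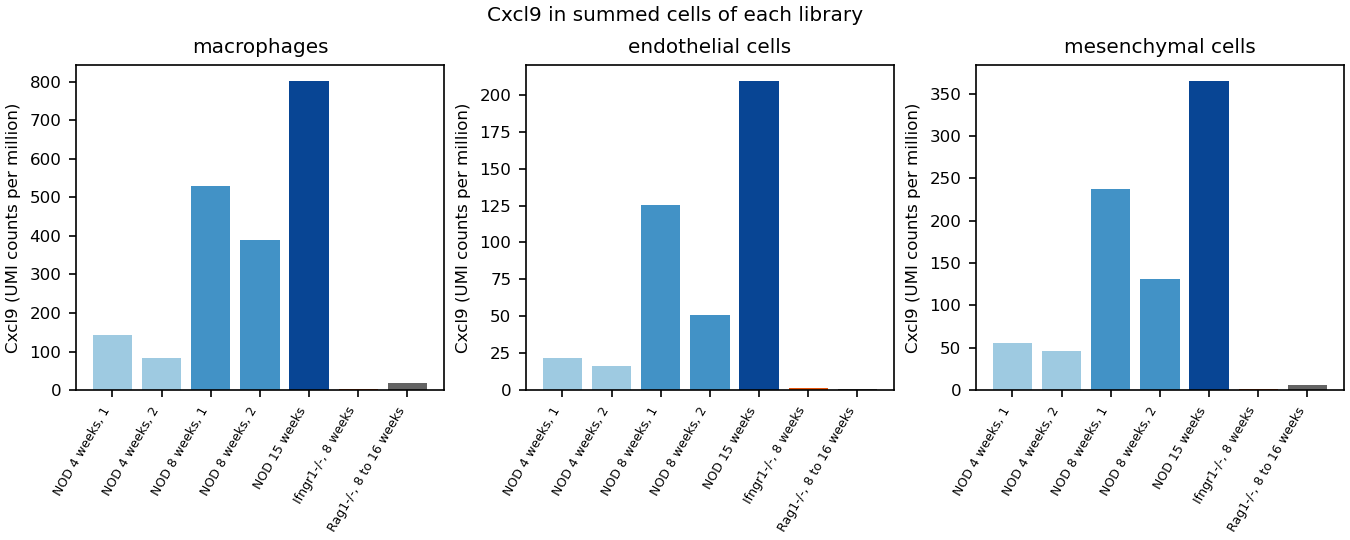
Cxcl9 (CPM) in macrophages, endothelial cells and mesenchymal cells of each library. Macrophages held 459 CPM on average at 8 weeks, 803 at 15 weeks, 3.66 in the Ifngr1-/- library and 19.2 in the Rag1-/- library.

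Antigen presentation moved with the interferon genes. All 20 members of the MHC class I and peptide loading list were higher in macrophages (0 rose, 18 rose when adjusted over the list alone, median 0.74, adjusted p = 3.8e-24). They were higher in endothelial cells (0 rose, 19 when adjusted over the list alone, median 0.94, adjusted p = 1.5e-36) and mesenchymal cells (2 rose, H2-Q7 at 1.54 ± 0.24 and H2-T23 at 1.35 ± 0.21, 20 when adjusted over the list alone, median 1.20, adjusted p = 1.1e-32). The 3 tests gave adjusted p = 0.22, adjusted p = 0.25 and adjusted p = 0.25 with an estimated correlation. With the block 13, 17 and 15 of them rose. The type I interferon list was higher in 21 of 23, 19 of 21 and 16 of 18 members (0, 0 and 2 rose, 10, 13 and 7 when adjusted over the list alone, medians 0.50, 0.62 and 0.53, adjusted p = 5.9e-10, 5.2e-16 and 6.1e-10). These tests gave adjusted p = 0.22, adjusted p = 0.25 and adjusted p = 0.25 with an estimated correlation. The 2 that rose in mesenchymal cells were Isg15 (1.33 ± 0.19, adjusted p = 0.032) and Ifit3 (1.45 ± 0.19, adjusted p = 0.026). MHC class II was higher in all 10 members in each of the 3 types (0 rose in each, 9, 4 and 0 when adjusted over the list alone, medians 0.77, 0.75 and 0.33, adjusted p = 2.1e-10, 2.5e-09 and 0.0014). The class II tests gave adjusted p = 0.22, adjusted p = 0.25 and adjusted p = 0.34 with an estimated correlation. In mesenchymal cells class II did not pass without 4-week replicate 2 (adjusted p = 0.87) or 8-week replicate 1 (adjusted p = 0.19).

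In stroma, the stromal cytokine and chemokine list was higher in 14 of 16 members in mesenchymal cells (median 0.81, adjusted p = 7.8e-13, and adjusted p = 0.25 with an estimated correlation). Of these, 2 rose, Vcam1 at 1.76 ± 0.23 and Cxcl9, and 10 did when adjusted over the list alone. The endothelial adhesion and activation list was higher in all 13 members in endothelial cells (median 1.55, adjusted p = 4.5e-13, and adjusted p = 0.25 with an estimated correlation). Among them 0 rose, and 6 did when adjusted over the list alone. The extracellular matrix list was lower in all 20 members in endothelial cells (median -1.45, adjusted p = 2.0e-14, and adjusted p = 0.26 with an estimated correlation). In the whole fit 0 fell, and 12 did when adjusted over the list alone. In mesenchymal cells 17 of 20 were lower (median -0.51, adjusted p = 5.0e-10, and adjusted p = 0.25 with an estimated correlation). By gene, 1 fell, Col4a1 at -1.14 ± 0.17, and 8 did when adjusted over the list alone. Matrix genes were also lower in all 19 members in macrophages (median -1.35, adjusted p = 3.7e-13, and adjusted p = 0.22 with an estimated correlation), where Col4a2 was 8.9 times as high in empty droplets as in cells. Of the members, 1 fell, and 12 did when adjusted over the list alone.

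In T cells, naive and central memory genes were lower at 8 weeks. The list was lower in CD8 T cells (0 of 12 members fell, 2 when adjusted over the list alone, median -0.70, adjusted p = 7.3e-05, and adjusted p = 0.54 with an estimated correlation). It was lower in CD4 T cells as well (0 fell, 1 when adjusted over the list alone, median -0.25, adjusted p = 0.026, and adjusted p = 0.77 with an estimated correlation). Without 4-week replicate 2, the library with the larger B cell share, it did not pass in CD8 (adjusted p = 0.39) or CD4 T cells (adjusted p = 0.082) and its direction turned. It did not pass without 8-week replicate 1 either (adjusted p = 0.23 in CD8 and 0.66 in CD4 T cells). The inhibitory receptor list was higher in 12 of 13 members in CD8 T cells (median 0.53, adjusted p = 5.6e-07, without 4-week replicate 2 0.23, and adjusted p = 0.51 with an estimated correlation). Of these, 0 rose, and 1 did when adjusted over the list alone, Havcr2 at 2.59 ± 0.61. All 20 cell cycle genes were higher too (0 rose, 0 when adjusted over the list alone, median 0.40, adjusted p = 5.8e-07, without 8-week replicate 1 0.26, and adjusted p = 0.51 with an estimated correlation). In CD4 T cells all 8 follicular helper genes were higher (median 0.69, adjusted p = 9.8e-05, without 8-week replicate 1 0.082, and adjusted p = 0.47 with an estimated correlation), with Tnfsf8 at 0.95 ± 0.23 and Il21 at 1.59 ± 0.66. Among them 0 rose, and 1 did when adjusted over the list alone. The regulatory T cell list was higher in 10 of 11 members (0 rose, 1 when adjusted over the list alone, median 0.30, adjusted p = 0.0080, without 4-week replicate 2 0.050, without 8-week replicate 1 0.69, and adjusted p = 0.56 with an estimated correlation). Ifng itself (GRCm38 chromosome 10, 118441046 to 118445892, plus strand, protein coding) was 157 ± 16.9 against 131 ± 7.51 CPM in CD4 T cells and 165 ± 24.8 against 144 ± 10.2 in CD8 T cells (SD, n = 2 each), with log2 fold changes of 0.25 ± 0.21 and 0.22 ± 0.25 that did not pass.

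Markers of other cell types moved in the same samples. T cell genes were higher in all 12 members in macrophages (0 rose, 2 when adjusted over the list alone, median 0.97, adjusted p = 1.2e-08). The same 12 were higher in endothelial cells (0 rose, 5 when adjusted over the list alone, median 0.83, adjusted p = 5.9e-09) and in mesenchymal cells (0 rose, 6 when adjusted over the list alone, median 1.02, adjusted p = 2.0e-11). The T cell list had adjusted p = 0.25, adjusted p = 0.26 and adjusted p = 0.25 with an estimated correlation. All 6 erythroid genes were lower in mesenchymal cells (median -4.45, adjusted p = 4.4e-20, and adjusted p = 0.25 with an estimated correlation), among them Hba-a1 (-4.63 ± 0.22, adjusted p = 1.5e-05). In the whole fit 4 fell, and 5 did when adjusted over the list alone. The endocrine list passed as lower in endothelial cells while its median (0.37) and mean (0.04) were above 0 (8 of 15 members higher, 0 changed, 0 when adjusted over the list alone, adjusted p = 0.0067, with the block 0.25, as higher at 3.3e-06 without 8-week replicate 1, and adjusted p = 0.57 with an estimated correlation). RNA quality genes, all mitochondrial transcripts, were lower in 11 of 12 members in endothelial cells (median -0.15, adjusted p = 0.011, without 4-week replicate 1 turned at 0.97, without 8-week replicate 2 0.28, and adjusted p = 0.55 with an estimated correlation). By gene, 0 fell, and 0 did when adjusted over the list alone. Dissociation and immediate-early genes were higher in all 18 members in mesenchymal cells (median 0.39, adjusted p = 8.9e-10, and adjusted p = 0.25 with an estimated correlation). Of the members, 1 rose, Dnajb1 at 1.62 ± 0.25, adjusted p = 0.040, and 6 did when adjusted over the list alone. Igj, the joining chain of secreted antibodies, rose in macrophages (4.10 ± 0.56, adjusted p = 0.046, with RLE size factors 0.064 and without the Rag1-/- library 0.062) and mesenchymal cells (4.40 ± 0.39, adjusted p = 0.0016), and was 14 times as high in empty droplets as in macrophages.

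By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 14 genes changed in macrophages (12 rose and 2 fell), 26 in mesenchymal cells (20 rose and 6 fell) and 0 in endothelial cells, CD4 and CD8 T cells. In these, 953, 371 and 311 had an unadjusted p under 0.05 and DESeq2 called 72, 0 and 0. With RLE size factors, or without the Rag1-/- library, 2 genes passed in macrophages. With the block, the counts in macrophages, mesenchymal cells, endothelial cells, CD4 and CD8 T cells were 413, 292, 494, 17 and 14. Leaving out 4-week replicates 1 and 2 and 8-week replicates 1 and 2 in turn gave 19, 8, 105 and 370 genes in macrophages and 135, 159, 67 and 114 in mesenchymal cells. In the same order it gave 0, 231, 1 and 14 in endothelial cells, 10, 22, 32 and 56 in CD4 T cells, and 0, 0, 16 and 49 in CD8 T cells. Of 125 list tests in the 5 types 80 passed, and 0 did with an estimated correlation.

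The second comparison set the 15-week library against the 4-week libraries and asks how far the changes extend later in the disease. In macrophages, Cxcl13 rose from 13.8 ± 13.8 CPM (SD, n = 2) to 2192 CPM (log2 fold change 7.34 ± 0.97 SE, adjusted p = 0.0077). Ccl8 rose from 69.5 ± 10.3 to 2783 CPM (5.32 ± 0.52, adjusted p = 0.0030) and Cxcl9 from 114 ± 42.3 to 803 CPM (2.81 ± 0.32, adjusted p = 0.0060). Of 21 lipid and phagolysosome genes 1 rose and 3 fell, the lipid receptor Trem2 (-2.09 ± 0.29, adjusted p = 0.0087), the lipase Lpl (-2.39 ± 0.27, adjusted p = 0.0060) and the scavenger receptor Cd36 (-2.32 ± 0.32, adjusted p = 0.0087). The elastase Mmp12 fell as well (-3.76 ± 0.35, adjusted p = 0.0022). In mesenchymal cells the protease inhibitor Slpi rose from 4.45 ± 0.542 to 1212 CPM (8.11 ± 0.30, adjusted p = 2.9e-06). The alarmin Il33 (4.84 ± 0.48, adjusted p = 0.00083) and the cytokine Il6 (2.40 ± 0.27, adjusted p = 0.0015) rose. In endothelial cells Glycam1, a carrier of L-selectin ligands on high endothelial venules, was at 0 UMIs at 4 weeks and 36.0 CPM at 15 weeks, at least 390-fold higher against a floor of 3 UMIs over the 4-week libraries (adjusted p = 0.0071).

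The interferon-gamma response list was higher in every measured member in the 3 non-lymphoid types. In macrophages 22 of 28 rose, 25 when adjusted over the list alone, with a median of 1.93 (adjusted p = 6.1e-31, and adjusted p = 0.22 with an estimated correlation). In endothelial cells 24 of 29 rose, 27 when adjusted over the list alone, with a median of 2.99 (adjusted p = 4.4e-56, and adjusted p = 0.19 with an estimated correlation). In mesenchymal cells 22 of 27 rose, 24 when adjusted over the list alone, with a median of 2.86 (adjusted p = 4.4e-39, and adjusted p = 0.23 with an estimated correlation). An example is Gbp5 (3.13 ± 0.36, adjusted p = 0.0060) in macrophages. In endothelial cells Cd274 (3.01 ± 0.22, adjusted p = 0.0043), Igtp (4.01 ± 0.30, adjusted p = 0.0043) and the ubiquitin-like modifier Ubd (6.06 ± 0.47, adjusted p = 0.0043) rose, as did Zbp1 (3.14 ± 0.29, adjusted p = 0.00067) and Ubd (8.52 ± 0.75, adjusted p = 0.00063) in mesenchymal cells.

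**Figure D3:**
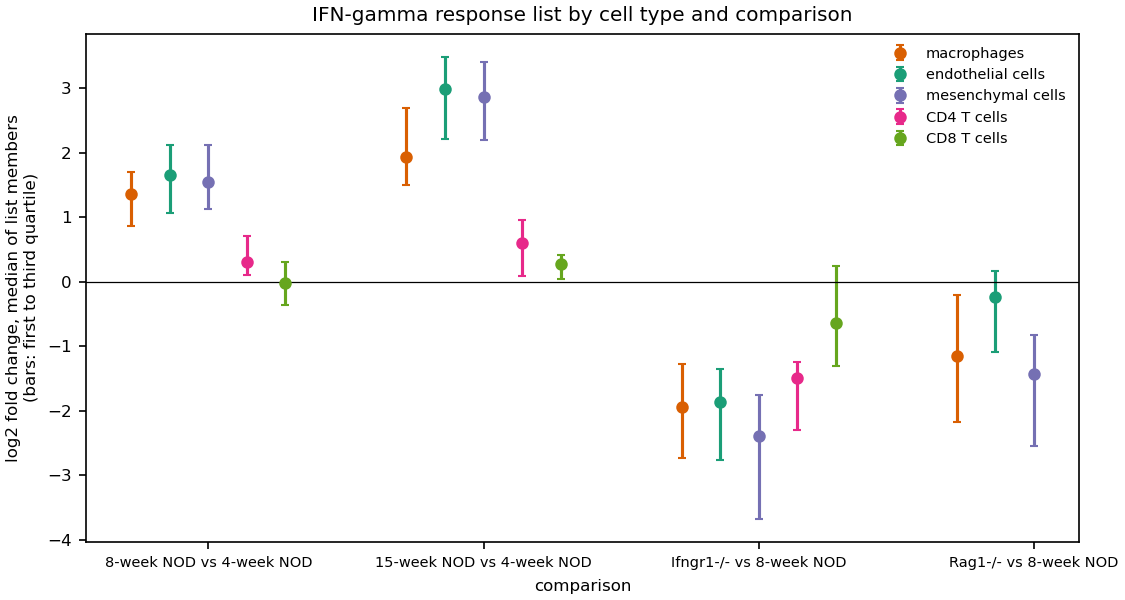
Median log2 fold change of the interferon-gamma response list, with bars from the first to the third quartile of its members, by cell type and comparison. In macrophages, endothelial cells and mesenchymal cells the medians are 1.36, 1.65 and 1.54 at 8 weeks, 1.93, 2.99 and 2.86 at 15 weeks, and -1.94, -1.86 and -2.39 in the Ifngr1-/- library.

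Antigen presentation genes rose in all 3 types. The MHC class I and peptide loading list had 15 of 20 members up in macrophages, 13 in endothelial cells and 20 in mesenchymal cells (19, 20 and 20 when adjusted over the list alone, medians 1.15, 1.70 and 2.32, adjusted p = 1.4e-21, 6.2e-45 and 1.4e-37). The class I tests gave adjusted p = 0.22, adjusted p = 0.18 and adjusted p = 0.23 with an estimated correlation. H2-Q7 rose by 3.04 ± 0.19 (adjusted p = 0.0041) in endothelial cells and 2.94 ± 0.27 (adjusted p = 0.00067) in mesenchymal cells. MHC class II genes were all higher (1, 3 and 1 of 10 rose, 9, 9 and 3 when adjusted over the list alone, medians 0.95, 1.93 and 0.71, adjusted p = 2.1e-08, 1.2e-16 and 2.7e-05). For class II they gave adjusted p = 0.22, adjusted p = 0.18 and adjusted p = 0.24 with an estimated correlation. Cd74, the class II invariant chain, rose in endothelial cells (2.23 ± 0.33, adjusted p = 0.040) and was 6.3 times as high in empty droplets as in those cells. The stromal cytokine and chemokine list rose in 11 of 16 members in mesenchymal cells (14 when adjusted over the list alone, median 2.12, adjusted p = 4.4e-20, and adjusted p = 0.23 with an estimated correlation). The endothelial adhesion and activation list rose in 6 of 13 members in endothelial cells (10 when adjusted over the list alone, median 3.18, adjusted p = 3.5e-17, and adjusted p = 0.18 with an estimated correlation). There Vcam1 rose by 3.18 ± 0.48 (adjusted p = 0.044) and Cxcl10 by 3.31 ± 0.30 (adjusted p = 0.0070).

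In macrophages the inflammatory cytokine and chemokine list was higher in 18 of 22 members (median 0.82, adjusted p = 3.1e-08, and adjusted p = 0.31 with an estimated correlation), with Ccl7 at 3.47 ± 0.26 and the prostaglandin synthase Ptgs2 at 3.43 ± 0.47. Of these, 8 rose and 1 fell, and 10 and 1 when adjusted over the list alone. The monocyte list was higher in all 12 members (median 0.91, adjusted p = 6.4e-06, and adjusted p = 0.22 with an estimated correlation). Among them 2 rose, Plac8 at 1.94 ± 0.29 and Ms4a4c at 1.40 ± 0.27, and 7 did when adjusted over the list alone. The lipid and phagolysosome list was lower (median -0.25, adjusted p = 0.020, without 4-week replicate 1 0.088, and adjusted p = 0.30 with an estimated correlation). When adjusted over the list alone, 1 rose and 6 fell. The member that rose is the fatty acid-binding gene Fabp5 (2.22 ± 0.28, adjusted p = 0.0066). The resident macrophage list did not pass (1 of 14 rose, 1 rose and 1 fell when adjusted over the list alone, median -0.003, adjusted p = 0.89).

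In CD4 T cells the follicular helper list was higher in 7 of 8 members (median 1.01, adjusted p = 7.6e-05, and adjusted p = 0.45 with an estimated correlation). By gene, 2 rose, and 3 did when adjusted over the list alone. The 2 were Tnfsf8, the ligand of CD30 (2.45 ± 0.24, adjusted p = 0.0069), and Sostdc1 (5.40 ± 0.92, adjusted p = 0.040), and Spp1 rose by 2.69 ± 0.41 (adjusted p = 0.040). The effector T cell list was lower in 14 of 19 members (median -0.23, adjusted p = 0.043, without 4-week replicate 1 0.21, and adjusted p = 0.45 with an estimated correlation). Of the members, 0 fell, and 2 did when adjusted over the list alone, with the block 5. In CD8 T cells the chemokine Ccl1 (GRCm38 chromosome 11, 82176657 to 82305690, minus strand, protein coding) fell from 198 ± 156 to 1.68 CPM (-6.76 ± 0.86, adjusted p = 0.0028). The inhibitory receptor list was higher in 9 of 13 members (0 rose, 7 when adjusted over the list alone, median 0.82, adjusted p = 1.5e-05, without 4-week replicate 2 0.080, and adjusted p = 0.44 with an estimated correlation). The naive and central memory list did not pass in CD4 T cells (0 of 12 changed, 0 when adjusted over the list alone, median 0.14, adjusted p = 0.17). It passed with the block (2 rose, adjusted p = 1.4e-05).

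The B and plasma cell list was higher in mesenchymal cells in all 10 members (median 1.30, adjusted p = 3.1e-06, and adjusted p = 0.27 with an estimated correlation), where Igj rose by 8.61 ± 0.40 and was 5.1 times as high in empty droplets as in cells. Of these, 3 rose, and 3 did when adjusted over the list alone. Endothelial capillary genes fell in macrophages (median -2.17, adjusted p = 1.3e-10, and adjusted p = 0.30 with an estimated correlation). Among them 1 of 15 rose and 10 fell, and 1 and 13 when adjusted over the list alone. The same list did not pass in endothelial cells themselves (0 of 16 changed, 0 when adjusted over the list alone, median -0.01, adjusted p = 1.0). Among the genes that fell in CD4 and CD8 T cells were vascular and matrix genes such as Col4a1 (-2.85 ± 0.43 and -3.12 ± 0.55) and the endothelial receptor Kdr (-2.30 ± 0.31 and -2.74 ± 0.34), which were between 6.1 and 8.4 times as high in empty droplets as in those cells. Erythroid genes fell in mesenchymal cells (4 of 6, 5 when adjusted over the list alone, median -7.08, or -5.75 with genes at 0 set to their bound, adjusted p = 9.2e-10, and adjusted p = 0.23 with an estimated correlation). Endocrine genes were lower in all 15 members in mesenchymal cells (median -2.67, or -2.45 with genes at 0 set to their bound, adjusted p = 5.2e-05, and adjusted p = 0.37 with an estimated correlation), with the insulin gene Ins2 at -2.70 ± 0.42. In the whole fit 2 fell, and 3 did when adjusted over the list alone. Of the RNA quality genes, 11 of 12 were lower in macrophages (median -0.23, adjusted p = 0.013, and adjusted p = 0.37 with an estimated correlation). By gene, 1 fell, mt-Atp8 at -1.38 ± 0.24, and 1 did when adjusted over the list alone.

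The edgeR test called 481 genes in macrophages (274 rose and 207 fell), 26 in CD4 T cells (7 and 19) and 30 in CD8 T cells (4 and 26). It called 103 in endothelial cells (97 and 6) and 282 in mesenchymal cells (230 and 52). With the block these counts became 864, 154, 65, 660 and 628. Without 4-week replicates 1 and 2 and 8-week replicates 1 and 2 in turn the counts were 287, 246, 1010 and 1016 in macrophages, 129, 150, 225 and 211 in CD4 T cells and 12, 2, 121 and 105 in CD8 T cells. They were 34, 149, 65 and 87 in endothelial cells and 655, 462, 493 and 517 in mesenchymal cells. Of 125 list tests 86 passed, and 0 with an estimated correlation.

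The third comparison set the Ifngr1-/- library against the 8-week NOD libraries and asks which of the changes need the interferon-gamma receptor. Cxcl9 fell in macrophages from 459 ± 100 CPM (SD, n = 2) to 3.66 CPM (log2 fold change -6.96 ± 0.53 SE, adjusted p = 0.0047). In mesenchymal cells it fell from 184 ± 74.6 to 1.86 CPM (-6.61 ± 0.56, adjusted p = 0.0030), and Cxcl10 from 130 ± 27.1 to 5.95 CPM (-4.45 ± 0.37, adjusted p = 0.0030). In CD4 T cells the chemokine Ccl1 rose from 94.8 ± 30.8 to 1159 CPM (3.62 ± 0.34, adjusted p = 0.0042). The enkephalin precursor Penk rose from 56.6 ± 10.1 to 457 CPM (3.02 ± 0.38, adjusted p = 0.016). In CD8 T cells Ccl1 was the 1 gene that passed, rising from 66.9 ± 33.7 to 787 CPM (3.68 ± 0.51, adjusted p = 0.036).

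Ifngr1 itself was lower without passing the test, at -1.02 ± 0.25 in macrophages (adjusted p = 0.31), -1.05 ± 0.27 in CD4 T cells (adjusted p = 0.47) and -1.28 ± 0.34 in CD8 T cells (adjusted p = 0.54). In endothelial cells it was lower by -1.30 ± 0.20 (adjusted p = 0.16, with the block 0.00062) and in mesenchymal cells by -1.50 ± 0.26 (adjusted p = 0.12, with the block 0.0037). Ifng did not pass in CD4 (-0.29 ± 0.27, adjusted p = 0.95) or CD8 T cells (0.98 ± 0.28, adjusted p = 0.66), with 330 CPM against 165 ± 24.8 in the latter.

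The interferon-gamma response list was lower in each of the 5 types. In macrophages all 28 members were lower, with a median of -1.94 (adjusted p = 2.1e-42, and adjusted p = 0.25 with an estimated correlation). Of them 5 fell, 25 when adjusted over the list alone and 15 with the block. In endothelial cells 28 of 29 were lower, with a median of -1.86 (adjusted p = 1.9e-55, and adjusted p = 0.28 with an estimated correlation). There 0 fell, 25 when adjusted over the list alone and 21 with the block. In mesenchymal cells all 27 were lower, with a median of -2.39 (adjusted p = 5.9e-41, and adjusted p = 0.29 with an estimated correlation). Here 4 fell, 24 when adjusted over the list alone and 17 with the block. In CD4 T cells 22 of 24 were lower (median -1.49, or -1.41 with genes at 0 set to their bound, adjusted p = 7.3e-15, and adjusted p = 0.60 with an estimated correlation). Of the members, 0 fell, and 17 did when adjusted over the list alone. In CD8 T cells 12 of 17 were lower (0 fell, 4 when adjusted over the list alone, median -0.64, adjusted p = 0.0090, and adjusted p = 0.79 with an estimated correlation). In macrophages Gbp5 (-4.24 ± 0.50, adjusted p = 0.024), Serpina3g (-4.80 ± 0.56, adjusted p = 0.024), and Zbp1 (-2.62 ± 0.26, adjusted p = 0.020) fell. In mesenchymal cells Zbp1 (-4.22 ± 0.45, adjusted p = 0.016) and Gbp2 (-2.60 ± 0.30, adjusted p = 0.020) fell. The genes with the smallest p in endothelial cells did not pass and did with the block. They include Cxcl10 (-5.11 ± 0.43, adjusted p = 0.057, with the block 1.2e-10), H2-Q7 (-2.47 ± 0.23, adjusted p = 0.057, with the block 4.4e-07) and Irgm2 (-2.45 ± 0.25, adjusted p = 0.082, with the block 4.6e-06).

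Related programs were lower as well. The MHC class I and peptide loading list was lower in all 20 members in macrophages, endothelial cells and mesenchymal cells (0 fell in each, 17, 14 and 16 when adjusted over the list alone, 10, 11 and 10 with the block, medians -1.03, -0.85 and -1.39, adjusted p = 2.9e-31, 3.3e-35 and 2.2e-34). Class I tests gave adjusted p = 0.25, adjusted p = 0.28 and adjusted p = 0.29 with an estimated correlation. The MHC class II list was lower in all 10 members in these types (0 fell in each, 0, 3 and 2 when adjusted over the list alone, medians -0.24, -0.83 and -0.39, adjusted p = 0.00066, 2.5e-09 and 0.00050). Class II tests gave adjusted p = 0.35, adjusted p = 0.28 and adjusted p = 0.43 with an estimated correlation. In mesenchymal cells class II did not pass with the block (adjusted p = 0.13). The type I interferon list was lower in 23 of 23, 21 of 21 and 16 of 18 members (0 fell in each, 9, 0 and 5 when adjusted over the list alone, medians -0.75, -0.46 and -0.48, adjusted p = 2.3e-13, 6.6e-14 and 1.4e-09). Type I tests gave adjusted p = 0.25, adjusted p = 0.28 and adjusted p = 0.29 with an estimated correlation. The lipid and phagolysosome list was higher in 17 of 21 members in macrophages (median 0.34, adjusted p = 0.00020, and adjusted p = 0.25 with an estimated correlation). Of these, 0 rose, and 2 did when adjusted over the list alone. There the lysozyme gene Lyz1 rose by 2.25 ± 0.25 (adjusted p = 0.024) and Ly6i (-5.93 ± 0.70, adjusted p = 0.024) and Plac8 (-3.61 ± 0.39, adjusted p = 0.024) fell.

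In CD8 T cells the inhibitory receptor list was higher in 10 of 13 members (median 0.53, adjusted p = 0.0016, and adjusted p = 0.79 with an estimated correlation). Among them 0 rose, and 1 did when adjusted over the list alone. Gzmk, a granzyme outside the list, was at -2.25 ± 0.38 and did not pass (adjusted p = 0.10). In CD4 T cells Zfp36l2, an mRNA decay factor, fell (-2.01 ± 0.30, adjusted p = 0.047), Wfdc18 was at 0 UMIs in the 8-week libraries and at least 49.0-fold higher (adjusted p = 0.037). The naive and central memory list was lower in 9 of 12 members (median -0.73, adjusted p = 0.0028, without 8-week replicate 2 0.098, and adjusted p = 0.79 with an estimated correlation). In the whole fit 0 fell, and 1 did when adjusted over the list alone.

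Markers of other cells moved here too. B and plasma cell genes were lower in macrophages (median -2.65, or -2.17 with genes at 0 set to their bound, adjusted p = 0.0014, and adjusted p = 0.50 with an estimated correlation). By gene, 0 of 10 fell, and 2 did when adjusted over the list alone, with the block 7. T cell genes were lower in 11 of 12 members there (0 fell, 0 when adjusted over the list alone, median -0.97, adjusted p = 4.6e-05, and adjusted p = 0.39 with an estimated correlation). Acinar cell genes, which encode digestive enzymes, were higher in all 6 members in mesenchymal cells (median 2.92, or 2.53 with genes at 0 set to their bound, adjusted p = 2.5e-09, and adjusted p = 0.29 with an estimated correlation). Of the members, 0 rose, and 4 did when adjusted over the list alone. Extracellular matrix genes were higher in all 19 members in macrophages (0 rose, 6 when adjusted over the list alone, median 1.38, adjusted p = 3.9e-14, and adjusted p = 0.27 with an estimated correlation). RNA quality genes did not pass in macrophages (0 of 12 changed, 0 when adjusted over the list alone, median 0.09, adjusted p = 0.35, and adjusted p = 0.75 with an estimated correlation).

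The edgeR test called 14 genes in macrophages (1 rose and 13 fell), 7 in CD4 T cells (6 and 1), 1 in CD8 T cells, 4 in mesenchymal cells, all lower, and 0 in endothelial cells. There 344 genes had an unadjusted p under 0.05 and DESeq2 called 40. With the block and the Ifngr1-/- library in the second batch, the counts were 117, 25, 3, 122 and 135. Leaving out 4-week replicates 1 and 2 and 8-week replicates 1 and 2 in turn gave 23, 18, 69 and 278 genes in macrophages, 36, 38, 23 and 89 in CD4 T cells and 1, 1, 7 and 47 in CD8 T cells. It gave 89, 86, 51 and 104 in mesenchymal cells and 0, 0, 2 and 14 in endothelial cells. Of 125 list tests 63 passed, and 0 with an estimated correlation.

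The fourth comparison set the Rag1-/- library against the 8-week NOD libraries. In the Rag1-/- library no cell was annotated as a CD4 or CD8 T cell, B cell or plasma cell. Macrophages in it carried more of the inflammatory genes Il1b, Il1a and Plau and less Cxcl9. Il1b rose from 387 ± 96.5 CPM (SD, n = 2) to 2374 CPM (log2 fold change 2.62 ± 0.27 SE, adjusted p = 0.0018), Il1a by 3.48 ± 0.22 (adjusted p = 0.00053) and Plau by 3.82 ± 0.24 (adjusted p = 0.00053). Cxcl9 fell in macrophages from 459 ± 100 to 19.2 CPM (-4.58 ± 0.43, adjusted p = 0.0015). It fell in endothelial cells by -7.01 ± 0.75 (adjusted p = 0.0045) and in mesenchymal cells by -4.90 ± 0.42 (adjusted p = 0.00040). The genotype shares its batch, barcode list and age range with no other library, so every difference here is also a difference between batches.

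The interferon-gamma response list was lower in macrophages, with 11 of 28 members falling and 2 rising (16 and 3 when adjusted over the list alone, median -1.15, adjusted p = 2.5e-05, and adjusted p = 0.56 with an estimated correlation). In mesenchymal cells it was lower too, with 16 of 27 falling and 3 rising (22 and 3 when adjusted over the list alone, median -1.43, adjusted p = 2.5e-08, and adjusted p = 0.46 with an estimated correlation). In endothelial cells it did not pass (6 of 29 fell and 3 rose, 10 and 4 when adjusted over the list alone, median -0.24, adjusted p = 0.33). Serpina3g fell in macrophages (-4.08 ± 0.50, adjusted p = 0.0030) and mesenchymal cells (-4.54 ± 0.53, adjusted p = 0.0012), and Gbp2 in mesenchymal cells (-2.61 ± 0.28, adjusted p = 0.00081). The type I interferon list was higher in all 3 types. In macrophages 14 of 23 rose (19 when adjusted over the list alone, median 1.17, adjusted p = 2.1e-10, and adjusted p = 0.46 with an estimated correlation). Ifit3 rose by 2.05 ± 0.24 (adjusted p = 0.0028) and Ifi27l2a by 2.26 ± 0.27 (adjusted p = 0.0030). In endothelial cells 6 of 21 rose (8 when adjusted over the list alone, median 0.51, adjusted p = 5.1e-05, and adjusted p = 0.48 with an estimated correlation), among them Isg15 at 1.31 ± 0.19 (adjusted p = 0.012). In mesenchymal cells 4 of 18 rose (10 when adjusted over the list alone, median 0.68, adjusted p = 0.00011, and adjusted p = 0.36 with an estimated correlation).

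MHC class I genes went opposite ways in endothelial and mesenchymal cells, and class II genes were lower in both. The MHC class I list was higher in endothelial cells (median 0.65, adjusted p = 1.3e-05, and adjusted p = 0.48 with an estimated correlation). Of these, 8 of 20 rose and 1 fell, and 10 and 1 when adjusted over the list alone. There H2-K1 rose from 1997 ± 134 to 5692 CPM (1.51 ± 0.20, adjusted p = 0.0092) and H2-Q7 by 1.52 ± 0.19 (adjusted p = 0.0066). In mesenchymal cells it was lower (5 of 20 fell, 7 when adjusted over the list alone, median -0.61, adjusted p = 2.9e-05, and adjusted p = 0.54 with an estimated correlation). There B2m fell from 2815 ± 622 to 497 CPM (-2.5 ± 0.32, adjusted p = 0.0020). The MHC class II list was lower in endothelial cells (4 of 10 fell, 9 when adjusted over the list alone, median -1.43, adjusted p = 2.0e-05, and adjusted p = 0.48 with an estimated correlation). It was lower in mesenchymal cells too (5 of 10 fell, 10 when adjusted over the list alone, median -1.79, adjusted p = 3.2e-06, and adjusted p = 0.36 with an estimated correlation).

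In macrophages the inflammatory cytokine list was higher (median 0.98, adjusted p = 0.0017, without 8-week replicate 2 0.062, and adjusted p = 0.56 with an estimated correlation), with Ccl4 at 1.95 ± 0.27 (adjusted p = 0.0042). Among them 10 of 22 rose and 3 fell, and 13 and 3 when adjusted over the list alone. The resident macrophage list was higher (median 0.45, adjusted p = 0.017, without 8-week replicate 1 0.068, and adjusted p = 0.56 with an estimated correlation), with Cd163 at 4.69 ± 0.90 (adjusted p = 0.014) and Mrc1 at 1.92 ± 0.25 (adjusted p = 0.0034). In the whole fit 5 of 14 rose and 1 fell, and the same when adjusted over the list alone. Cell cycle genes were lower (median -0.91, adjusted p = 2.8e-05, and adjusted p = 0.46 with an estimated correlation), with Birc5 at -3.54 ± 0.29 (adjusted p = 0.0011). By gene, 9 of 20 fell, and 13 fell and 2 rose when adjusted over the list alone. This fall follows the annotation, as 60 cycling cells with macrophage levels of C1q carry the NKT label there. Of C1q-high cells 1.60% were cycling under the macrophage label and 4.73% with these added, against 4.03% and 4.27% at 8 weeks. Ly6i (-7.93 ± 0.76, adjusted p = 0.0015), Cst7 (-5.89 ± 0.55, adjusted p = 0.0015) and the chemokine Cxcl13 (-7.74 ± 1.37, adjusted p = 0.010) fell. Ifngr1 rose by 0.88 ± 0.23 (adjusted p = 0.041).

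Some early response genes rose, and such genes respond to tissue dissociation. Of the dissociation list, 5 of 18 rose in macrophages (11 when adjusted over the list alone, median 0.84, adjusted p = 1.3e-05, and adjusted p = 0.46 with an estimated correlation). In endothelial cells 3 of 18 rose (3 when adjusted over the list alone, with 1 falling, median 0.42, adjusted p = 0.0081, and adjusted p = 0.48 with an estimated correlation), and in mesenchymal cells 9 of 18 (11 when adjusted over the list alone, median 0.94, adjusted p = 6.3e-07, and adjusted p = 0.36 with an estimated correlation). Atf3 rose in each (2.64 ± 0.35, 2.02 ± 0.22 and 3.14 ± 0.24, adjusted p = 0.0035, 0.0045 and 0.00027).

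T cell transcripts were lower in the other cell types of this library. Of 12 T cell genes, 10, 11 and 12 fell in macrophages, endothelial cells and mesenchymal cells (12 in each when adjusted over the list alone, medians -4.82, -6.40 and -7.05, or -4.27, -4.71 and -5.44 with genes at 0 set to their bound, adjusted p = 4.7e-07, 2.0e-06 and 2.5e-08). The T cell list gave adjusted p = 0.46, adjusted p = 0.48 and adjusted p = 0.36 with an estimated correlation. The plasma cell gene Igj was at 0 UMIs and at least 223-fold lower in macrophages (adjusted p = 0.0032). Endocrine genes were higher in macrophages (14 of 15 rose, 15 when adjusted over the list alone, median 2.78, adjusted p = 4.4e-12, and adjusted p = 0.46 with an estimated correlation). Glucagon, Gcg, was at 677 CPM against 55.1 ± 23.7 (3.62 ± 0.37, adjusted p = 0.0018). RNA quality genes did not pass in macrophages (median 0.55, adjusted p = 0.17, and adjusted p = 0.61 with an estimated correlation). Of the members, 3 of 12 rose and 2 fell, and 6 and 2 when adjusted over the list alone. Processed pseudogenes and other pseudogenes made up 34 of the 824 genes that fell in macrophages (4.13%) and 81 of the 12099 tested (0.669%), and only 1 of the 630 that rose.

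The edgeR test called 1454 genes in macrophages (630 rose and 824 fell), 1398 in endothelial cells (619 and 779) and 1490 in mesenchymal cells (567 and 923), and DESeq2 called 809, 1135 and 519. Leaving out 4-week replicates 1 and 2 and 8-week replicates 1 and 2 in turn gave 1530, 1431, 1657 and 1283 genes in macrophages. It gave 1712, 2171, 451 and 356 in endothelial cells and 2426, 2380, 1256 and 1178 in mesenchymal cells. With the 15-week NOD library as the control the counts were 1003, 649 and 1166. Of 77 list tests 42 passed, and 0 with an estimated correlation. T cells could not be compared, as no cell of this library carries a T cell label.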

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

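The tests of differences between cell types, of the batch for B cells and for the interferon-gamma list, and of lymphoid genes in NKT-labelled cells without macrophage levels of C1q were chosen only after the results were seen. For the lymph node or blood test, the condition on the T cell share was made stricter after its values were seen.

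The interferon and MHC lists changed by different amounts in different cell types, which was tested directly for 4 lists and 3 pairs of types in 3 comparisons (36 tests, 4 residual degrees of freedom, 20 passing, the lowest adjusted p 0.0725 with an estimated correlation). Each value is the median difference between log2 fold changes. From 4 to 8 weeks, endothelial cells exceeded macrophages by 0.23 in the interferon-gamma list (adjusted p = 0.00053) and 0.12 in MHC class I (adjusted p = 0.020). Mesenchymal cells exceeded macrophages by 0.39 in the interferon-gamma list (adjusted p = 0.020) and 0.49 in class I (adjusted p = 8.8e-06) and differed by -0.38 in class II (adjusted p = 0.00049). Endothelial minus mesenchymal values were -0.25 for class I (adjusted p = 0.0075) and 0.40 for class II (adjusted p = 3.5e-05). In Ifngr1-/- against 8-week NOD, endothelial minus macrophage values were 0.15 for type I interferon (adjusted p = 0.039) and -0.40 for class II (adjusted p = 4.0e-05), and endothelial minus mesenchymal values 0.24 for class I (adjusted p = 0.0032) and -0.31 for class II (adjusted p = 0.0075). In Rag1-/- against 8-week NOD, endothelial minus macrophage values were 0.77 for the interferon-gamma list (adjusted p = 2.6e-06), -0.41 for type I (adjusted p = 0.00049), 0.32 for class I (adjusted p = 1.7e-06) and -1.35 for class II (adjusted p = 4.8e-09). Mesenchymal minus macrophage values there were -0.51 for type I (adjusted p = 0.0092), -1.05 for class I (adjusted p = 1.1e-14) and -1.50 for class II (adjusted p = 8.3e-11), and endothelial minus mesenchymal values 0.78 for the interferon-gamma list (adjusted p = 1.9e-13) and 1.39 for class I (adjusted p = 4.1e-34).

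Barcodes outside the annotation that were as deep as annotated ones numbered 62, 191 and 307 in the 4-, 8- and 15-week libraries of the first batch, 168 and 148 in the 4- and 8-week libraries of the second, 140 in the Ifngr1-/- library and 1180 in the Rag1-/- library. The 3662 barcodes marked as aggregates and 340 as contamination were not analysed here.

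Cells annotated as NKT were 12.9% of leukocytes without Rag1, more than in any NOD library. Of these, 69 of 308 had macrophage levels of C1q genes, 60 of them with cell cycle transcripts, so lymphoid genes were compared over the other 239. Remaining T cells stay open, since Cd3d, Cd3g and Trac together were at 30.7% of their level in NKT-labelled cells of NOD mice (14.8%, 46.3% and 7.33% each), between the limits set for the test. NK cells stay open, since Ncr1, Klrb1c and Klre1 were at 24.8% of their level in NOD NK cells, with an upper 95% limit of 27.4%. Over all 308 cells both planned sums were under 25% of their references (390 against 2195 CPM and 343 against 2236 CPM), values lowered by the macrophage RNA in them. Several kinds of innate lymphoid cell under this label were not tested, as that library uses no other lymphoid label. The batch and barcode list cannot be told apart from the genotype.

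B cells were 0.980% of leukocytes in 4-week replicate 1 and 24.7% in replicate 2. A batch effect cannot be told apart from other causes. The lowest B cell share in the second batch was 1.07%, in the Ifngr1-/- library, whose genotype differs. Lymph node or blood cells in replicate 2 may contribute. Naive and central memory genes were higher there by medians of 0.98 in CD4 and 1.49 in CD8 T cells (0.39 and 0.83 at 8 weeks). T cells would then also be more of the leukocytes other than B cells. Their shares were 17.1% and 17.7% with overlapping intervals, but leave out 44 and 197 macrophage-T cell aggregates, so the source stays open. Differences between mice were not tested.

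The interferon-gamma response list was higher at 8 than at 4 weeks in endothelial and mesenchymal cells. Macrophage RNA caught in these cells is argued against, as it could bring at most 5.03% of the rise. Batch is argued against, because within either batch the first quartile of the members' differences was at least 0.69. Signalling through the interferon-gamma receptor is the hypothesis these values are in line with, since without Ifngr1 at 8 weeks the list lay under the 4-week mean in both types, with the higher median at -0.25. In that 1 library T cells were 15.4% of leukocytes other than B cells, against 33.6% and 27.0% in the 8-week NOD libraries, so a direct effect on stroma was not separated from a smaller infiltrate.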

How the results depend on the processing

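The setting without genes higher in empty droplets, the fit without the Rag1-/- library, the block for the Ifngr1-/- library and all tests of conventional dendritic cells (cDC) were chosen only after the results were seen. The 15-week, Ifngr1-/- and Rag1-/- groups hold 1 library each, and 2 residual degrees of freedom remain, or 1 with the block. Leaving out 1 replicate makes the other a lone library, assumed to vary like the rest. Of 12664 gene values 10593 kept call and direction, 1652 became stronger, 345 weaker, 69 moved and 5 reversed. Of 2563 list values 1755 kept theirs, 791 weakened and 17 reversed. Of 327 cell share values 265 kept theirs, 32 weakened, 18 became stronger and 12 moved. Of 294 counts of calls 120 stayed within 1.5 times, 124 were higher and 50 lower. The cause of these changes was not tested. Counts below follow the order 8 against 4 weeks, 15 against 4 weeks, Ifngr1-/- and Rag1-/- against 8 weeks, where all are given. The starting counts are 14, 481, 14 and 1454 in macrophages, 0, 26 and 7 in CD4 T cells, 0, 30 and 1 in CD8 T cells, 0, 103, 0 and 1398 in endothelial cells, 26, 282, 4 and 1490 in mesenchymal cells and 2, 55, 50 and 341 in cDC.

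The batch as a replicate block gave, at 8 and 15 weeks, 413 and 864 genes in macrophages, 17 and 154 in CD4 T cells, 14 and 65 in CD8 T cells, 494 and 660 in endothelial cells, 292 and 628 in mesenchymal cells and 48 and 158 in cDC. With the Ifngr1-/- library in the second batch it gave 117, 25, 3, 135, 122 and 130 in these types. Of the list tests that had passed, the block kept 182 at 8 and 15 weeks and lost 7, and in Ifngr1-/- it kept 64 and lost 9. In cell shares at 15 weeks 1 type passed instead of 4. Among the results printed, the block changed no call other than those given beside them. No paired analysis was possible for Rag1-/- because that library shares no batch number with another.

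Without a filter on low counts, macrophages had 583, 1324, 291 and 2585 genes, CD4 T cells 19, 260 and 49, CD8 T cells 22, 145 and 23, endothelial cells 549, 723, 131 and 2959, mesenchymal cells 298, 789, 145 and 2388, and cDC 147, 531, 313 and 949. DESeq2 called 87, 49 and 809 in macrophages (8 weeks, Ifngr1-/-, Rag1-/-), 18 in CD8 T cells at 15 weeks, 72, 179 and 40 in endothelial cells (8 weeks, 15 weeks, Ifngr1-/-), 45, 162, 25 and 519 in mesenchymal cells, and 12 and 220 in cDC (8 weeks, Rag1-/-). RLE size factors gave 2 genes in macrophages at 8 weeks, as did the fit without the Rag1-/- library. With at most 200 cells per library, macrophages had 32, 219, 22 and 511, CD4 T cells 7 and 13 (15 weeks, Ifngr1-/-), endothelial cells 3, 62 and 300 (8 weeks, 15 weeks, Rag1-/-), mesenchymal cells 87, 36 and 705 (8 weeks, Ifngr1-/-, Rag1-/-) and cDC 8 and 105 (8 weeks, Ifngr1-/-). There Cxcl10 in endothelial cells of Rag1-/- reversed to 1.23.

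Leaving out 1 library gave lowest and highest counts at 8 weeks of 8 and 370 in macrophages, 10 and 56 in CD4 T cells, 0 and 49 in CD8 T cells, 0 and 231 in endothelial cells, 67 and 159 in mesenchymal cells and 0 and 111 in cDC. In the same order they were 246 and 1016, 129 and 225, 2 and 121, 34 and 149, 462 and 655, and 13 and 388 at 15 weeks, and 18 and 278, 23 and 89, 1 and 47, 0 and 14, 51 and 104, and 64 and 295 in Ifngr1-/-. In Rag1-/- they were 1283 and 1657 in macrophages, 356 and 2171 in endothelial cells, 1178 and 2426 in mesenchymal cells and 470 and 509 in cDC. For cell shares they were 0 and 1, 0 and 3, 0 and 1, and 7 and 11.

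At 8 weeks, some lists reversed when 1 library was left out, given with the lowest and highest adjusted p of the 4 fits. Without 4-week replicate 1 these were, in CD4 T cells, lipid and phagolysosome (2.45e-07 and 0.973, the reversed value) and macrophage genes (1.44e-14 and 0.973, reversed). In endothelial cells they were B and plasma cell (4.33e-07 and 0.605, reversed), macrophage (3.20e-10 and 0.577, reversed) and RNA quality genes (0.000662 and 0.970, reversed). In mesenchymal cells they were lipid and phagolysosome (1.45e-06 and 0.616, reversed) and B and plasma cell genes (2.41e-07 and 0.515, with 0.0555 reversed). Without 4-week replicate 2 it was naive and central memory genes in CD4 (2.91e-16 and 0.664, with 0.0817 reversed) and CD8 T cells (2.04e-15 and 0.393, reversed). Without 8-week replicate 1 it was lipid and phagolysosome in CD4 T cells (0.690) and endocrine genes in CD8 T cells (6.91e-12 and 0.370, with 0.000229 reversed) and endothelial cells (3.12e-17 and 0.0319, with 3.27e-06 reversed).

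Without genes higher in empty droplets, fewer genes were tested. Macrophages had 54, 269 and 28 (8 weeks, 15 weeks, Ifngr1-/-), CD4 T cells 1 and 11 (15 weeks, Ifngr1-/-), CD8 T cells 1, 4 and 13, endothelial cells 25 and 18 (8 weeks, Ifngr1-/-), mesenchymal cells 18 (Ifngr1-/-) and cDC 1 and 7 (8 and 15 weeks). Of the list tests 46, 42, 38 and 14 passed, against 80, 86, 63 and 42. Reversed were effector T cell genes in macrophages of Rag1-/- (0.776), lipid and phagolysosome in CD4 T cells at 8 weeks (0.868) and in endothelial cells at 15 weeks (0.331), resident macrophage genes there (0.544), and endothelial capillary identity in mesenchymal cells of Rag1-/- (0.729). With an estimated correlation 0 list tests passed in each comparison, and with fry 2, 2, 2 and 4.

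With 15-week NOD as control of Rag1-/-, endothelial cells had 649 genes, and in mesenchymal cells Rtp4 (-0.0186), Hbb-bs (2.27), Hba-a2 (4.67) and Hba-a1 (0.20) reversed. For cell shares, 4 and 11 types passed at 15 weeks and in Rag1-/-, and 0 in the others. All identified cells as denominator gave 7, 10 and 4 in the first 3 comparisons, TMM 0 at 15 weeks and 7 in Rag1-/-, and a non-lymphoid denominator 3 in Rag1-/-.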

Other observations

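Conventional dendritic cells were compared after the data were first seen, so all tests in this paragraph were chosen then, while the test of age genes in the last paragraph was written in advance. From 4 to 8 weeks the chemokine Ccl17 fell in them from 1808 to 387 CPM (log2 fold change -2.22 ± 0.25 SE, adjusted p = 0.024), and at 15 weeks it was lower still (-9.07 ± 0.50 against 4 weeks, adjusted p = 5.6e-05). The interferon-gamma response list was higher in 24 of 27 members at 8 weeks (0 rose, 14 when adjusted over the list alone, median 0.82, adjusted p = 6.4e-16, and adjusted p = 0.42 with an estimated correlation). Without Ifngr1 all 27 were lower than in 8-week NOD (9 fell, 23 when adjusted over the list alone, median -2.54, or -2.27 with genes at 0 set to their bound, adjusted p = 2.8e-29, and adjusted p = 0.29 with an estimated correlation). Lyz1 rose there by 7.23 ± 0.40 (adjusted p = 5.0e-05) and Cxcl9 fell (-4.81 ± 0.43, adjusted p = 0.0029). Macrophage markers were higher in all 11 members in these cells (3 rose, 8 when adjusted over the list alone, median 1.46, adjusted p = 5.1e-12, and adjusted p = 0.29 with an estimated correlation). In the Rag1-/- library Plau (5.68, adjusted p = 0.00097) and Il1b (3.29, adjusted p = 0.00097) rose in dendritic cells as in macrophages. The edgeR counts were 2, 55, 50 and 341 genes in the 4 comparisons. Without 4-week replicates 1 and 2 and 8-week replicates 1 and 2 in turn they were 2, 0, 13 and 111 from 4 to 8 weeks, 13, 101, 388 and 324 at 15 weeks and 86, 91, 64 and 295 without Ifngr1.

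CD8 T cells held 50.1% and CD4 T cells 28.0% of 721 Ifng UMIs in 8-week replicate 1. They held 70 and 172 in 8-week replicate 2. In the Rag1-/- library NKT-labelled cells held 96.9% of 131. Cxcl13 came mostly from macrophages, with 90.7% of 8539 UMIs at 15 weeks, and totals of 206 and 58 in the 4-week libraries. Ccl1 had 984 UMIs in the Ifngr1-/- library and 195 and 187 in the 8-week NOD libraries.

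Genes that rose with age outside the interferon and MHC lists were followed in the Ifngr1-/- library. The 100 genes with the largest rise from 4 to 8 weeks in the first batch were compared between the Ifngr1-/- and the 8-week NOD library of the second batch, so selection and test used different libraries. Their median difference was -0.42 in macrophages (84 lower), -0.14 in endothelial cells (74 lower) and -0.16 in mesenchymal cells (69 lower), at percentile 0 of 10000 random lists matched on mean level in each of the 3 types. The 100 genes with the largest fall had medians of 0.49, 0.33 and 0.41, at percentile 100. Percentile 0 cannot separate a need for the IFN-gamma receptor from fewer lymphocytes in this 1 library, since lymphocytes also rose in the first batch.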
